A study of Mus musculus with 27 samples.

How the data were processed

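RNA sequencing of mouse dorsal skin was analysed from 1 deposited table of 54532 genes. It holds 27 columns of read counts per gene, which the authors deposited without normalization per the file headers, and 27 columns of FPKM (fragments scaled by gene length and sequencing depth) made by the authors. Each FPKM equals the count divided by gene length and by 1 constant per library, which lay between 0.922 and 1.08 of the count total. The authors' deposited table also gives log2 fold changes and p-values of their own comparisons, and the tool behind them is not given in the sources used here. Per the submitters' processing notes, Bowtie 0.12.2 and the mm9 build were used. Of the 54495 genes found in GENCODE M21, 98.33% had the same coordinates as in that GRCm38 annotation, so coordinates are given as in the table, on GRCm38. Per the labels' protocols, libraries were made with the Illumina TruSeq RNA kit. The same protocol text speaks of retina, whereas the tissue is labelled dorsal skin. The highest mean of 20 retina genes was 9.21 CPM and their median 0.11 CPM, against 2117 CPM for the skin keratin Krt14.

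Groups were taken from the labels. The comparisons, tests, alternatives, 39 gene lists and rule for named genes were fixed before the data were examined. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 17232 genes and 99.86% of the reads. Counts were scaled with TMM and fitted over all 27 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) in R 4.3.3. Group means and SDs are of CPM after TMM scaling, and values of single libraries are of CPM before it, except in the outlier tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of single genes in the report are from this test. Standard errors are the absolute log2 fold change over the square root of the F statistic. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. As alternatives, lists were tested with an estimated correlation, with which no list was called in any comparison, and with fry. The retina list and the keratin-associated protein list had 3 and 2 tested members and were not tested as sets.

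Named genes were, for each comparison, the 5 largest and 5 smallest log2 fold changes among called genes with a mean of at least 1 CPM, leaving out clone and locus names. To these were added the 2 members with the smallest p from up to 8 called lists, and the thyroid hormone genes Thra, Thrb, Klf9, Hr, Thrsp, Dio1 and Dio2. For TDM versus Vehicle, Shh, Axin2, Lef1, Lgr5, Mki67, Fgf18 and Krt25 were also named.

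Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE scaling, no filter, a filter at a mean of 1 CPM, a 2-fold threshold, only the 2 groups compared, the replicate number as a block, 3 surrogate variables (sva 3.50.0), the mean log2 CPM of the skeletal muscle list as a covariate, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and each library left out. Fits without Vehicle replicates 7 and 8, and without 3, 7 and 8, were added after seeing the data. The fits were tested on simulated counts of 17232 genes for TDM versus Vehicle. edgeR recovered 74 of 100 genes changed 2-fold and 52 of 100 changed 1.5-fold, with 6 false calls, and DESeq2 recovered 77 and 63 with 20 false calls. The simulated genes were drawn independently of each other, without shifts in tissue content between libraries. These counts therefore need not hold for the real libraries. No 2 libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom over 108 pairs being 9.51. Figures were drawn with matplotlib 3.10.9.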

Results

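Dorsal skin of C3H mice was profiled by RNA sequencing after topical treatment with TDM10842, described by the submitters as a thyroid hormone receptor agonist. The 27 libraries fall into 3 groups of 9. Blank skin received nothing, Vehicle skin received the solvent, and TDM skin received the compound in that solvent. Vehicle and TDM skin received 2 applications of 60 µL, at 0 and 24 h. Count totals ran from 15705220 to 17599066 reads in Blank, 15412332 to 17001952 in Vehicle and 15996657 to 17357395 in TDM. Of 54532 annotated genes, 34892 had a read in at least 1 library and 17232 were tested. The labels do not say whether the 9 libraries of a group came from separate animals, so p-values measure the spread between these libraries, part of which may be technical.

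The first 2 principal components of log2 CPM, the read counts scaled to sequencing depth, held 32.1% and 24.5% of the variance of the 2000 most variable genes. On the second, TDM libraries had a mean score of -25.9 ± 7.63 (SD, n = 9), Blank libraries 13.8 ± 9.28 and Vehicle libraries 12.1 ± 17.9. Vehicle replicate 7, at -24.13, lay among the TDM libraries, and Vehicle replicate 8 lay below the remaining 7 Vehicle libraries.

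**Figure D1:**
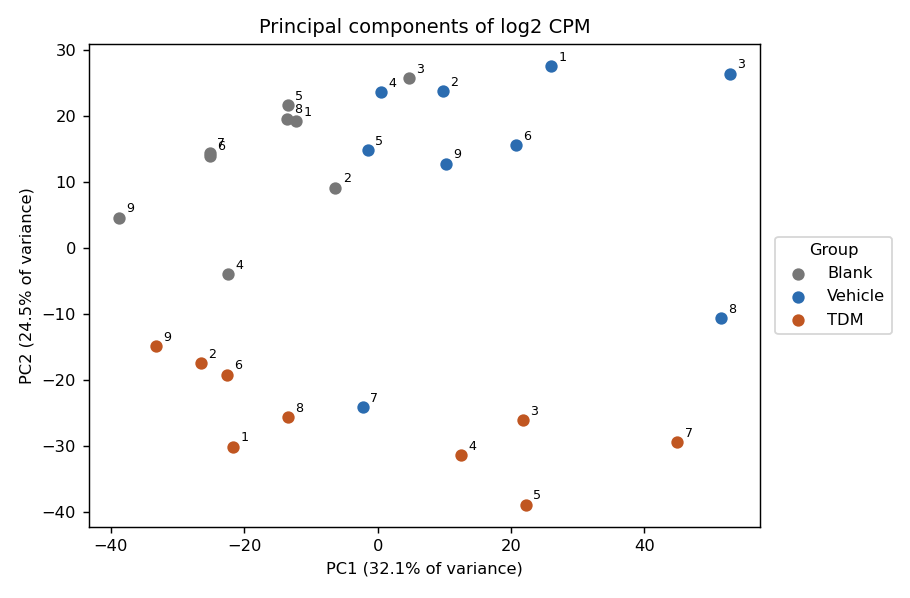
Scores of the 27 libraries on the first 2 principal components of log2 CPM (axes: component scores, with the percent of variance each holds); points are libraries, numbered by replicate and coloured by group. TDM libraries run from -38.9 to -14.92 on the second component, and Vehicle replicate 7 lies among them at -24.13.

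TDM was compared with Vehicle to find the transcripts that differed between skin given the compound and skin given the solvent alone. Most genes of dividing cells and part of those of the growing hair follicle were higher in TDM skin, and most muscle genes were lower. Of the 40 proliferation genes, 37 rose and none fell (all 40 rose when adjusted over the list alone), with a median log2 fold change of 0.85. Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, rose from 25.3 ± 13.6 to 56.7 ± 13.8 CPM (SD, n = 9 each; log2 fold change 1.17 ± 0.23 SE, adjusted p = 0.00192). Mcm7, part of the replicative helicase, rose 1.69-fold (adjusted p = 0.00243). The list was called by camera, but its adjusted p was 0.344 with an estimated correlation. Of 12 hedgehog pathway genes, 8 rose and none fell (8 adjusted over the list alone; adjusted p = 0.344 with an estimated correlation). Gli2, a transcription factor of that pathway, rose from 25.5 ± 15.8 to 65.3 ± 9.96 CPM (adjusted p = 0.0013), and Smo rose 1.37-fold (adjusted p = 0.00407). Shh itself had a mean of 26.1 ± 20.5 CPM in TDM and 7.07 ± 14.5 in Vehicle, and did not pass the test (log2 fold change 1.89, adjusted p = 0.119); without Vehicle replicate 8 it passed (3.30, 0.00791). Shh stood at 17.8 and 41.5 CPM in Vehicle replicates 7 and 8 and at most 1.02 in the other Vehicle libraries.

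Further follicle lists were called as higher, while those of the bulge and hair germ (2 of 26 genes higher and 3 lower, 2 and 1 adjusted over the list alone) and of BMP, FGF and TGF-beta signals of the resting follicle (2 of 25 higher, 4 higher and 3 lower adjusted over the list alone) were not (camera adjusted p = 0.372 and 0.36), although the second passed with fry (0.0338). Of 29 dermal papilla genes, 13 rose and 1 fell (15 and 2 adjusted over the list alone), among them Prom1 at 2.70-fold (adjusted p = 0.000401) and Sox18 at 2.36-fold (adjusted p = 0.00113). Of 16 melanocyte and pigment genes, 10 rose, with 13 adjusted over the list alone. Tyrp1, an enzyme of melanin synthesis, rose from 33.2 ± 30.4 to 85.5 ± 41.3 CPM (adjusted p = 0.0152). Of 9 hair shaft and root sheath keratins, 5 rose, by either adjustment. Krt25, a keratin of the inner root sheath, rose from 0.78 ± 2.01 to 7.20 ± 9.19 CPM (log2 fold change 3.20, adjusted p = 0.00836). The change was 2.46 without TDM replicate 5 and 5.95 without Vehicle replicate 7, which held 6.26 CPM, where replicate 8 held 0.0649 and no other Vehicle library more than 0.238. In the Wnt and beta-catenin list 15 of 50 genes rose and 3 fell (17 and 3 adjusted over the list alone), and in the list of anagen matrix, cortex and inner root sheath 11 of 23 rose and 1 fell (15 and 2 adjusted over the list alone). Each of these 5 lists was called by camera and had an adjusted p of 0.344 with an estimated correlation. Axin2 (log2 fold change 0.08, adjusted p = 0.633), Lgr5 (0.14, 0.615), Lef1 (0.79, 0.0824), Mki67 (0.61, 0.0744) and Fgf18 (-1.15, 0.0536) did not pass the test. Lef1 passed without Vehicle replicate 8 (adjusted p = 0.00406), Mki67 without Vehicle replicate 8 (0.00343) or 7, and Fgf18 in 9 of the 27 fits with 1 library left out (lowest adjusted p = 0.0206). Without Vehicle replicates 7 and 8, an alternative chosen after seeing the data, 40 of 40 proliferation genes, 9 of 12 hedgehog genes and 13 of 16 pigment genes rose. Shh, Tyr and Mki67 were high in both of these libraries. Leaving both out therefore raises such changes by construction and adds no support.

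Most muscle genes and part of the basal keratinocyte genes were lower, and part of the epidermal differentiation genes were higher. Of 29 skeletal muscle genes, 24 fell and none rose (24 adjusted over the list alone; adjusted p = 0.387 with an estimated correlation). Myh2, a fast myosin heavy chain, fell from 564 ± 213 to 219 ± 81.5 CPM (adjusted p = 0.00238), and Tpm2 was at 0.479 of its Vehicle level (adjusted p = 0.00294). Of 53 oxidative phosphorylation genes, 32 fell and 1 rose (41 and 1 adjusted over the list alone; adjusted p = 0.53 with an estimated correlation). Cox6c fell (adjusted p = 0.0141), and Cox6a1 was the member that rose, at 1.28-fold (adjusted p = 0.0142). Of 40 epidermal differentiation genes, 20 rose, with 24 adjusted over the list alone (adjusted p = 0.632 with an estimated correlation). Klk7, a protease of the outer epidermis, rose from 42.9 ± 16.5 to 196 ± 98.9 CPM (adjusted p = 9.61e-05), and Klk5 rose 7.95-fold (adjusted p = 0.00137). Of 31 fibroblast and matrix genes, 18 rose (24 adjusted over the list alone, adjusted p = 0.53 with an estimated correlation), among them Col6a1 at 2.12-fold (adjusted p = 0.00431) and Col6a2 at 2.05-fold (adjusted p = 0.0059). In TDM versus Blank neither the fibroblast nor the oxidative phosphorylation list was called (camera adjusted p = 0.909 and 0.527). There 3 of 31 and 0 of 53 genes rose and none fell, with median log2 fold changes of 0.16 and -0.01. The mean muscle score, the mean log2 CPM of the tested skeletal muscle genes, was 9.75 ± 0.589 in Vehicle, 9.42 ± 0.443 in Blank and 8.91 ± 0.472 in TDM (SD, n = 9 each). With this score as a covariate the epidermal differentiation list, TDM versus Vehicle, turned direction and lost its call (median log2 fold change -0.22 rather than 1.20, adjusted p = 0.101), as did the oxidative phosphorylation list, TDM versus Vehicle (adjusted p = 0.833). The fibroblast and extracellular matrix list, TDM versus Vehicle (0.176), and the mitochondrial transcripts list, TDM versus Vehicle (0.833), lost their call without turning. The skeletal muscle and fast fibre lists share their genes with the score, which removes their change by construction. Camera also called as lower the lists of fast muscle fibre, mitochondrial transcripts, basal keratinocyte, circadian clock and sebaceous gland, in which 8 of 9, 4 of 24, 8 of 15, 3 of 20 and 7 of 24 genes fell (8, 3, 9, 3 and 8 adjusted over the list alone), while 3 sebaceous genes rose. The call of the sebaceous list ended without any 1 of 5 libraries. Their adjusted p was 0.387 for muscle fibre and clock and 0.53 for the others with an estimated correlation.

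Genes named for thyroid hormone action differed among themselves. Dio2 (ENSMUSG00000007682, chromosome 12, 90724552 to 90738438), which activates thyroid hormone by deiodination, rose from 2.35 ± 1.07 to 6.81 ± 1.96 CPM (log2 fold change 1.53 ± 0.23 SE, adjusted p = 8.73e-05, above the Vehicle median in 9 of 9 libraries). Thrsp, a regulator of lipid synthesis, rose from 104 ± 103 to 305 ± 93.3 CPM (adjusted p = 0.0109). Klf9 (log2 fold change 0.00, adjusted p = 1), Hr (0.05, 0.799), Thra (-0.05, 0.72) and Thrb (-0.26, 0.0679) did not pass the test, although Thrb passed in 9 of the 27 fits with 1 library left out (lowest adjusted p = 0.0202). Dio1 had 52 reads over all 27 libraries and was not tested. Of 32 genes in the thyroid hormone response list, 5 rose and 3 fell, by either adjustment, and the list was not called (adjusted p = 0.977 with an estimated correlation). Its median log2 fold change was -0.07, while camera's direction was higher.

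In all, 4090 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2070 higher and 2020 lower in TDM, and 649 of them changed at least 2-fold. The highest rises among named genes were Ighg1, Sprr4, Rptn, Klk13 and Cacng4. In the authors' deposited log2 fold changes, Sprr4 and Rptn stood at 4.33 and 3.92 here, and at -4.58 and -3.36 in Vehicle versus Blank. Both comparisons share the Vehicle libraries, which were low for Sprr4 and Rptn. Ighg1 (ENSMUSG00000076614, chromosome 12, 113325240 to 113330523), an immunoglobulin heavy chain constant region, rose from 0.12 ± 0.12 to 10.6 ± 6.29 CPM (log2 fold change 6.32 ± 0.53 SE, adjusted p = 1.34e-08); it has close relatives in the genome, and reads shared with them were not resolved. Cacng4, a calcium channel subunit, rose 13-fold (adjusted p = 6.97e-08), and Klk13 rose 13.5-fold (adjusted p = 0.00029). The largest falls were Dmbt1, Lypd8, Slc12a1, Muc2 and Gapdh. Vehicle replicate 3 held 51.3 CPM of Dmbt1, 46.8 of Lypd8 and 34.9 of Muc2, and stood out for other intestinal-type transcripts. Vehicle replicates 4 and 6 held 5.84 and 3.37 CPM of Dmbt1, 11.7 and 3.96 of Lypd8 and 18.2 and 10.1 of Muc2, where no TDM library held more than 0.872, 1.56 and 1.44. Without replicate 3, and with replicates 4 and 6 kept, their log2 fold changes were -2.36, -2.74 and -2.99 rather than -4.74, -4.37 and -3.82 (adjusted p = 0.0599, 0.0468 and 0.0151), and Slc12a1 (-3.61) fell most of the 5. Gapdh ranged between 14.4 and 706 CPM among Vehicle libraries and has many near-identical pseudogenes, so its counts are uncertain; its log2 fold change was -4.16 rather than -3.39 without TDM replicate 2. With the muscle score as a covariate, the number of TDM versus Vehicle genes changed was 246, of which 222 were among the 4090. The median absolute log2 fold change of the 4090 genes was then 0.252 rather than 0.536, with a median SE of 0.141 rather than 0.149, and 3900 kept their sign. Of 39 named genes 21 lost their call with this covariate, among them Rrm2, Gli2, Smo, Tyrp1, Krt25, Thrsp, Klk5, Klk13 and Col6a1. Myh2 and Tpm2, also among the 21, are part of the score. The 39 include Shh, Axin2, Lgr5, Lef1, Mki67, Fgf18, Klf9, Hr, Thra and Thrb, which had no call to lose. Camera called 16 of 37 lists, and random splits of the same libraries gave up to 21.

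**Figure D2:**
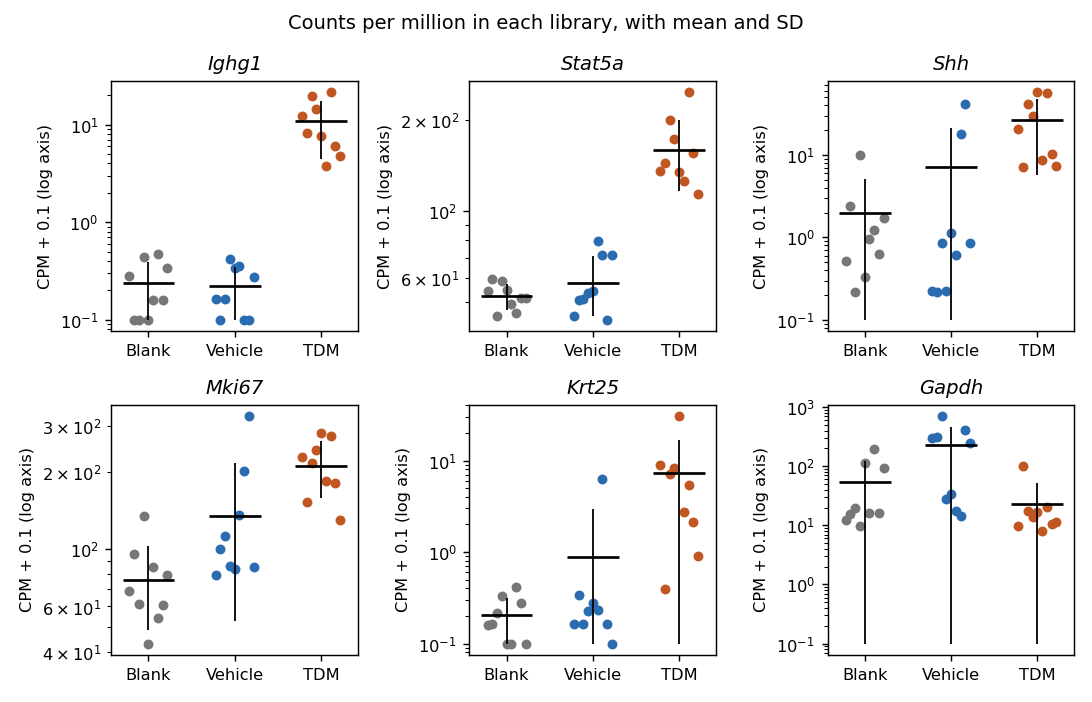
CPM of 6 genes in each library (vertical axes: CPM plus 0.1, log scale; horizontal axes: group); points are libraries, horizontal lines group means and vertical lines 1 SD, stopped at 0. Ighg1 is at 3.67 CPM or more in every TDM library, while Shh is high in 2 Vehicle libraries, at 17.8 and 41.5 CPM.

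Vehicle was compared with Blank for the effect of the solvent and its application. Part of the genes of the outer epidermis were lower in Vehicle skin. Of 40 epidermal differentiation genes, 21 fell and none rose (38 adjusted over the list alone), with a median log2 fold change of -1.83 (adjusted p = 0.414 with an estimated correlation). Ivl, a precursor of the cornified envelope, fell from 40.6 ± 22.5 to 11.4 ± 6.32 CPM (SD, n = 9 each; adjusted p = 0.0323). Klk7 fell from 138 ± 74.1 to 42.9 ± 16.5 CPM (adjusted p = 0.0322). Sprr4, Lipn, P2ry4, Cldn23 and Rptn had the largest falls, and Sprr4 went from 17.4 ± 18.6 to 0.73 ± 0.72 CPM (adjusted p = 0.0323). Of 31 fibroblast and matrix genes 3 fell (10 adjusted over the list alone; adjusted p = 0.589 with an estimated correlation), including Mmp2 at 0.414 and Fmod at 0.345 of the Blank level (adjusted p = 0.0379 and 0.0377). Hdc, a mast cell enzyme, fell to 0.429 of the Blank level (adjusted p = 0.0331), and Vegfc fell to 0.495 (adjusted p = 0.0323). Of 53 oxidative phosphorylation genes 1 rose, Cycs (41 adjusted over the list alone; adjusted p = 0.645 with an estimated correlation), and of 10 mast cell genes 1 fell, Hdc (8 adjusted over the list alone; adjusted p = 0.559 with an estimated correlation). Dbh, Mycbpap, Hist1h3d, Trim72 and Tnni3 had the largest rises among named genes. Camera called 17 lists, among them proliferation and skeletal muscle, in which no gene passed the test (adjusted p = 0.775 each with an estimated correlation). Without Vehicle replicates 7 and 8 the median log2 fold change of the proliferation genes was 0.11 rather than 0.51 (camera adjusted p = 0.0469), and without replicates 3, 7 and 8 the list was not called (0.148). With the muscle score as a covariate, the basal keratinocyte list, Vehicle versus Blank (adjusted p = 0.159), and the mitochondrial transcripts list, Vehicle versus Blank (0.275), lost their call.

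In all, 475 genes were called, 154 higher and 321 lower in Vehicle, against 4468 at an unadjusted p under 0.05. The smallest adjusted p was 0.0322, and the call of each called gene named here ended without any 1 of at least 8 libraries. In edgeR the number of Vehicle versus Blank genes changed was 0 without Blank replicate 4, 6 or 9 or Vehicle replicate 1, 3, 6 or 8, 1 without Blank replicate 7, 261 without Blank replicate 1, 275 without Vehicle replicate 9, 868 without Blank replicate 3, 849, 923 and 1299 without Vehicle replicate 4, 5 and 7, and 852 without TDM replicate 7. It was 9 with the muscle score as a covariate, 54 without Vehicle replicates 7 and 8, and 0 without Vehicle replicates 3, 7 and 8, and the fits that called 0 genes had 2803 to 4322 at an unadjusted p under 0.05. Dio2 (log2 fold change 0.08, adjusted p = 0.847), Thrsp (0.34, 0.615), Klf9 (-0.39, 0.0867), Hr (-0.14, 0.504), Thra (-0.07, 0.619) and Thrb (0.13, 0.424) did not pass the test.

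TDM was compared with Blank for compound and solvent together. All 40 proliferation genes rose, by either adjustment, with a median log2 fold change of 1.42 (adjusted p = 0.169 with an estimated correlation). Birc5, a mitotic regulator, rose from 10.9 ± 2.83 to 31.5 ± 11.4 CPM (SD, n = 9 each; adjusted p = 8.79e-05). Of 29 dermal papilla genes, 15 rose and 1 fell, by either adjustment (adjusted p = 0.206 with an estimated correlation). Rspo3, a Wnt pathway agonist, rose 4.24-fold (adjusted p = 0.000156), and Wif1, a secreted Wnt inhibitor, rose 2.69-fold (adjusted p = 0.00011). Of 12 hedgehog genes 8 rose (9 rose and 1 fell when adjusted over the list alone; adjusted p = 0.257 with an estimated correlation), among them Hhip at 3.49-fold (adjusted p = 0.000299). Of 9 hair shaft and root sheath keratins 6 rose, by either adjustment (adjusted p = 0.169 with an estimated correlation), and Krt73 went from 0.12 ± 0.11 to 21.9 ± 26.1 CPM (log2 fold change 7.43, adjusted p = 0.000215), with 6.77 without TDM replicate 5.

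Part of the genes of the sebaceous gland, which secretes lipid into the follicle, were lower. Of 24 such genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.257 with an estimated correlation). Scd3, a fatty acid desaturase, fell from 583 ± 159 to 81.9 ± 40 CPM (adjusted p = 1.06e-06), and Mc5r, a melanocortin receptor, fell to 0.338 of its Blank level (adjusted p = 3e-07). Of 40 epidermal differentiation genes 2 fell, Krt1 and Aloxe3 (0 adjusted over the list alone), calls that ended without any 1 of 6 and of 11 libraries. Of 29 skeletal muscle genes 2 fell, Myh2 and Tnni1, by either adjustment, and without Blank replicate 3 Tnni1 did not pass (log2 fold change -1.03 rather than -2.09, adjusted p = 0.179). The adjusted p of either list was 0.696 with an estimated correlation. Dio2 rose 3.06-fold (adjusted p = 4.47e-05) and Thrsp 3.72-fold (adjusted p = 0.00284). Klf9 was at 0.764 of its Blank level (adjusted p = 0.0473), a call that ended without any 1 of 14 libraries. Hr, Thra and Thrb did not pass the test (adjusted p = 0.702, 0.379 and 0.43). Mup7, among the largest falls, had a log2 fold change of -1.18 rather than -4.67 and an adjusted p of 0.584 without Blank replicate 6, its call ended without any 1 of 8 libraries, and its gene family holds near copies. Of 16 pigment genes 9 rose, of 50 Wnt genes 17 rose and 1 fell, and of 30 xenobiotic metabolism genes 6 fell (10, 23 and 3, and 6 adjusted over the list alone; adjusted p = 0.334, 0.281 and 0.14 with an estimated correlation).

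In all, 2793 genes were called, 1996 higher and 797 lower in TDM, and the number of TDM versus Blank genes changed was 3233 with the muscle score as a covariate. TDM and Vehicle shared 80 calls in the same direction against Blank, 46 higher and 34 lower, and 4 in opposite directions. Independent lists would share 32.7. With the Blank libraries split between the comparisons, the median of 20 splits was 0 (0 to 13). The covariance of the fold changes across genes was 0.0642, against a simulated median of 0.0224 and a median of 0.0473 with the controls split (-0.00563 to 0.0788). Their correlation was 0.368, against 0.478 to 0.523 in the simulations and a median of 0.262 with the controls split (-0.0227 to 0.469). The simulations drew each gene independently in unchanged groups, whereas genes here were correlated, at an estimated 0.804 within the proliferation list. The simulated ranges can therefore be too narrow, and a shared signal cannot be read from them.

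**Figure D3:**
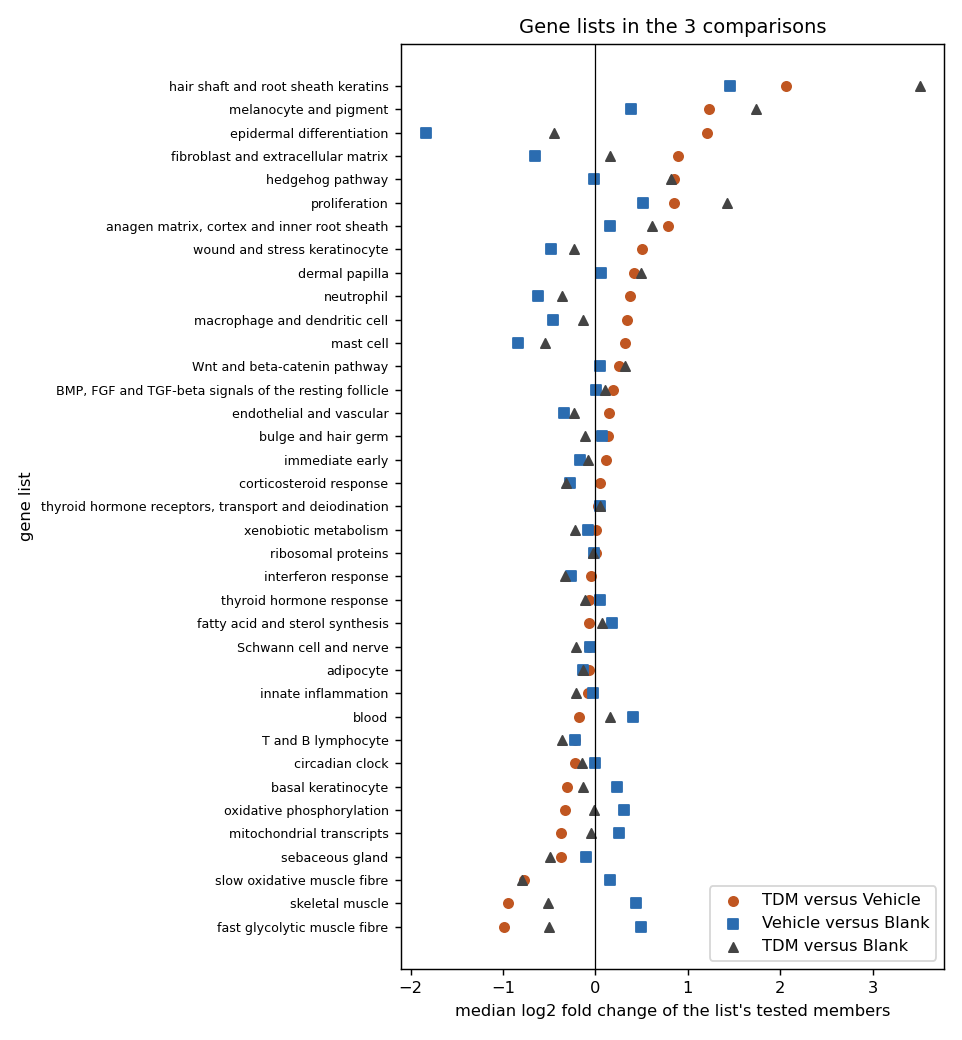
Median log2 fold change of the tested members of each gene list (horizontal axis) in the 3 comparisons; each row of the vertical axis is a list, ordered by TDM versus Vehicle. The epidermal differentiation list lies at -1.83 in Vehicle versus Blank and 1.20 in TDM versus Vehicle.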

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

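The tests of the first pattern, the keratinocyte test of the second and both tests of the third were chosen after the results were seen, and the muscle tests of the first pattern replaced one on the muscle scores alone. The intestinal test was written before its values were seen.

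In each group the library farthest from the others was tested with Dixon's ratio for each named gene and the count totals. Of 234 groups 16 passed, where chance gives about 11.7. In CPM after TMM scaling, Vehicle replicate 7 gave 6 of them, with Cox6a1 at 246 CPM, Dio2 at 4.95, Krt25 at 6.14, Krt73 at 17.5, Slc12a1 at 0 and Tnni3 at 0.814. Vehicle replicate 8 stood apart for Lef1 at 45.6 CPM, Vehicle replicate 5 for Mup7 at 72.4 and Vehicle replicate 3 for Tpsab1 at 0.0673. In Blank, replicate 5 stood apart for Cox6c at 324 CPM, replicate 8 for Muc2 at 23.2 and replicate 4 for Slc24a5 at 2.6. In TDM, replicate 6 stood apart for Dbh at 0.549 CPM, replicate 2 for Gapdh at 97.1, replicate 1 for Smo at 182 and replicate 7 for Vegfc at 3.45.

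Some follicle growth-phase transcripts were high in Vehicle replicates 7 and 8, Shh at 17.8 and 41.5 CPM and Tyr at 16.5 and 22.2, while Krt25 was high in replicate 7 alone, and mislabelled TDM libraries may be the source. Over 375 genes that part all TDM from all Blank libraries, on a scale with Blank at 0 and TDM at 1, the medians of these libraries were 0.916 and 1, as such a mislabelling predicts, and those of the other Vehicle libraries ran from -0.0943 to 0.346. A second test, added after the first, held out each TDM library in turn: Vehicle replicates 7 and 8 lay inside the Blank range at 9.99% and 18.1% of the genes, where held-out TDM libraries ran from 1.83% to 14.4% in 8 cases and reached 41.8% for TDM replicate 9, so that replicate 8 lies within their range through that library alone. Against it, Ighg1 had no read in either library and at least 3.67 CPM in every TDM library, Cacng4 (1.53 and 2.01 CPM) and Stat5a (71.7 and 43.6) lay below the lowest TDM library, at 5.34 and 114, and so did Krt25 in replicate 8 (0.0649 against 0.291), while the genes of both tests include growth-phase genes, which animals in that phase would share. The muscle score of replicate 7 lay -2.3 SD from the other Vehicle libraries, but less muscle raises other transcripts alike. Less muscle is argued against as the whole source there, since the lower quartile of the anagen list lay 0.428 log2 above the upper quartile of basal keratinocyte genes (medians 0.769 and -0.636). In replicate 8 these quartiles overlapped (-0.163), so the quartiles could not decide. Its muscle score, however, lay 0.868 SD above the other Vehicle libraries, which argues against less muscle as the source there. Mislabelling and a difference in hair cycle stage between animals stay open, and the latter was not tested.

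Transcripts of intestinal type stood out in Vehicle replicate 3, with Dmbt1 at 51.3 CPM. Of 33 intestinal epithelium genes with a read, 75.8% were highest in this library, which suggests RNA of intestinal epithelium in it, with Reg3b at 23.1 CPM against at most 2.04 in any other library, while Muc2 was also at 18.2 and 10.1 CPM in Vehicle replicates 4 and 6 and 23 in Blank replicate 8. Skin also expresses some of these genes, such as Fcgbp, at a median of 315 CPM in the other libraries. The library also held 32 reads of Y-linked genes, where no other library reached 10. Blank replicate 8 held 6 such reads, and Blank replicate 6 and Vehicle replicates 4 and 6 held 3 each. All remaining libraries, every TDM library among them, held 0. In Vehicle replicate 3, basal keratinocyte genes stood at 1.35 times their level in the other Vehicle libraries. This argues against a whole library of another tissue.

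Part of the epidermal differentiation genes were lower in Vehicle than in Blank (median log2 fold change of the list -1.83), and part were higher in TDM than in Vehicle (1.20). A smaller share of the whole epidermis is argued against, since basal keratinocyte genes had a median of 0.238 in Vehicle versus Blank, with quartiles of 0.182 and 0.34. Basal genes cannot tell whether the outer layers alone made up less of the sample. A larger share of muscle would lower other transcripts alike. It is argued against as the whole source of the fall in Vehicle versus Blank, since the epidermal differentiation quartiles were -2.23 and -1.37, far below those of basal genes. With the muscle covariate the epidermal median was -1.32, between the bounds set for and against muscle share, so a partial role of muscle was not settled. In TDM versus Vehicle the epidermal median went to -0.219 with this covariate. An effect of the solvent, which the design names, stays open and untested.

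The gene counts were compared with 100 splits of the same 18 libraries, the real one included. For 4090 calls in TDM versus Vehicle, 475 in Vehicle versus Blank and 2793 in TDM versus Blank, 1 split, the real one, gave as many, and the highest others gave 144, 2 and 252. Random splits thus seldom gave such counts. The splits treat the libraries as independent, which the labels do not state, and cannot tell treatment from another difference between the groups. The Vehicle versus Blank count also went to 0 without any 1 of 7 libraries. For the counts of lists called by camera, chance cannot be excluded: 30, 15 and 26 of 100 splits gave as many as the real 16, 17 and 16, and the highest others gave 21, 24 and 23. Single lists differed in TDM versus Vehicle. A median change as large came in 1 split, the real one, for proliferation, and in 8 for epidermal differentiation. A camera p as small came in 5 and 54 splits.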

How the results depend on the processing

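The fits without several Vehicle libraries were chosen after seeing the data, and the cause of a changed count was not tested unless stated. The number of TDM versus Vehicle genes changed was 6917 with limma voom, 649 with the 2-fold threshold, 246 with the muscle covariate and 1775 with surrogate variables. The number of Vehicle versus Blank genes changed was 1437 with DESeq2, 226 with limma voom, 2 with no filter, 167 with the 2-fold threshold, 9 with the muscle covariate, 40 with surrogate variables, 54 without Vehicle replicates 7 and 8, and 0 without Vehicle replicates 3, 7 and 8. The number of TDM versus Blank genes changed was 5261 with limma voom and 604 with the 2-fold threshold. The 2-fold threshold keeps fewer genes by construction. Calls shared in the same direction by both comparisons against Blank went from 80 to a median of 0 over 20 splits of the controls into 5 and 4 (0 to 13), and those in opposite directions from 4 to a median of 0 (0 to 28). Fewer Blank libraries per comparison can lower these counts too.

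Lists called went to 0 in each comparison with an estimated correlation, and with fry to 5 in Vehicle versus Blank and 9 in TDM versus Blank. In TDM versus Vehicle fry called 20 lists rather than 16: epidermal differentiation lost its call (0.0838), and 5 gained one, namely slow muscle fibre (0.0338), BMP, FGF and TGF-beta signals (0.0338), wound and stress keratinocyte (0.0473), neutrophil (0.0425) and thyroid hormone receptors, transport and deiodination (0.0425). Of 101 values of named genes, 88 kept their side and direction with DESeq2, 99 with RLE scaling, 57 with the muscle covariate and 69 with surrogate variables.

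Leaving out 1 library gave 3064 to 5522 genes for TDM versus Vehicle, 0 to 1299 for Vehicle versus Blank and 2289 to 3071 for TDM versus Blank, and 15 to 19, 14 to 19 and 13 to 18 lists. With the replicate block the number of TDM versus Vehicle genes changed was 3946, of Vehicle versus Blank genes changed 598 and of TDM versus Blank genes changed 2621. Same-numbered libraries correlated between -0.399 and 0.382 in their deviations, and 3 of 27 correlated best with their own number, as many as chance gives, so the numbers do not pair them.

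Signs turned for genes not called in either setting. Klf9, TDM versus Vehicle, was at -0.0109 with DESeq2 and RLE scaling, -0.00055 with limma voom, -0.01098 with no filter, -0.001063 with the stricter filter, -0.008441 with the replicate block, -0.01141 and -0.01177 with FPKM, -0.03193 with surrogate variables, -0.06817 without Vehicle replicates 7 and 8 and -0.1084 without 3, 7 and 8, and between -0.09723 and 0.04839 with 1 library left out. Hr, TDM versus Vehicle, was at -0.02284 and -0.02209 without those libraries and between -0.02318 and 0.1143 with 1 left out, and Thra, TDM versus Vehicle, at 0.02464 with the muscle covariate and 0.003449 with surrogate variables. Hr, TDM versus Blank, was at 0.07445 with surrogate variables. Dio2, Vehicle versus Blank, was at -0.1348 with limma voom, -0.1526 and -0.2353 without those libraries, -0.009496 with surrogate variables and between -0.1329 and 0.1602 with 1 left out. Thrsp, Vehicle versus Blank, was at -0.131 and -0.1631 with FPKM, -0.1069 without Vehicle replicates 7 and 8 and between -0.1523 and 0.4901 with 1 left out. Lists turned direction and lost their call with the muscle covariate for the epidermal differentiation list, TDM versus Vehicle (adjusted p = 0.101), the oxidative phosphorylation list, TDM versus Vehicle (0.833), and the fast glycolytic muscle fibre list, TDM versus Blank (0.877). Of 49 lists called, 36 kept their call with this covariate, and 4 more in TDM versus Vehicle, 4 in Vehicle versus Blank and 2 in TDM versus Blank lost it without turning. The skeletal muscle and fast fibre lists are made of genes of the covariate, so their lost calls follow by construction. With surrogate variables this held for the adipocyte list, Vehicle versus Blank (0.511), the skeletal muscle list, Vehicle versus Blank (0.646), and the fast glycolytic muscle fibre list, Vehicle versus Blank (0.795).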

Other observations

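The genes and lists here were chosen after the results were seen. The test of antibody-secreting cells was also chosen after, and that of the peroxisome list before its value was known. Kallikreins, serine proteases of which several act in the outer epidermis, were among the genes called: 7 of 8 tested rose in TDM versus Vehicle and 6 of 8 fell in Vehicle versus Blank (adjusted p = 0.0561 and 0.102 with an estimated correlation). The median log2 fold change of the 8 in TDM versus Vehicle was 2.69, and 1.38 with the muscle covariate. In TDM versus Blank 3 of 8 rose (adjusted p = 0.287 with an estimated correlation), with a median of 0.557, and 0.0246 with the muscle covariate, and Klk5 stood at 28 CPM in TDM, 3.5 in Vehicle and 21.2 in Blank. Klk5 and Klk7 also belong to the epidermal differentiation list. Klk8 rose from 14.1 ± 3.25 to 73.9 ± 15.8 CPM (SD, n = 9 each; adjusted p = 3.23e-10) and kept its call with the muscle covariate (adjusted p = 3.22e-08), as did Klk7 and Klk9 (0.0278 and 0.000231), while Klk5, Klk6, Klk10 and Klk13 lost theirs (0.238, 0.21, 0.49 and 0.0718). Stat5a, a transcription factor of cytokine signalling, rose from 58 ± 10.9 to 156 ± 40.6 CPM (adjusted p = 1.77e-08), while Stat5b stood at 124 and 120 CPM (adjusted p = 0.726). Cyp17a1, an enzyme of steroid synthesis, rose from 17.4 ± 5.11 to 80.3 ± 51.9 CPM (adjusted p = 8.16e-05).

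Single genes of lipid metabolism were lower in TDM than in Vehicle, while the fatty acid elongation list (4 of 19 higher and 7 lower) and the fatty acid and sterol synthesis list (5 of 30 higher and 3 lower) were not called (camera adjusted p = 0.123 and 0.754). Mgll, which cleaves monoglycerides, fell from 852 ± 230 to 339 ± 33.8 CPM (adjusted p = 2.38e-06). Elovl3 and Hacd2, of fatty acid elongation, fell from 82.4 ± 30.2 to 20 ± 8.35 and from 176 ± 52.5 to 64.6 ± 13.9 CPM (adjusted p = 1.17e-05 and 5.34e-06), while Elovl6 rose (adjusted p = 0.0198, and 0.103 with the muscle covariate). Each of Mgll, Elovl3 and Hacd2 kept its call with the muscle covariate (adjusted p = 0.000158, 0.00101 and 0.000669). Of 53 peroxisome genes 19 fell and 2 rose, with a median log2 fold change of -0.183, and of -0.0795 with the muscle covariate. That peroxisomal expression fell as a set may hold, but the adjusted p was 7.45e-07 with the preset and 0.204 with an estimated correlation, which leaves it open.

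Ighg1 rose 80-fold, while 2 of 11 other genes of antibody-secreting cells passed the test, Ighm and Prdm1 (adjusted p = 0.0313 and 0.00943), and neither passed with the muscle covariate (0.394 and 0.314). More such cells could raise Ighg1, but the median log2 fold change of the 11 was 0.134 against 6.32 for Ighg1, and Igkc stood at 8.57 ± 5.81 and 7.8 ± 6.3 CPM (adjusted p = 0.875). A transcript of the constant region made without antibody secretion, or reads of another origin, was not tested.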
